A study of Mus musculus with 17 samples.

How the data were processed

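Bronchoalveolar lavage cells of A/J mice were measured on 17 Affymetrix Mouse430_2 arrays, 1 RNA sample to an array, with 6 arrays from untreated controls and 11 from urethane-treated mice. The deposited values are probe set intensity values on a linear scale from the MAS5 algorithm, per the submitters' processing notes, which name no version. The mean intensity of each deposited array after trimming 2% at each end was 500, so the authors' scaling was kept. Scan files gave the chip lot and scan day, and were used only for those.

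The tables held 45101 probe sets, of which 64 were control probe sets. By the platform annotation 34945 of the others had 1 gene symbol, 932 had several and 9160 had none; probe sets with several or none were not named. Of the genes tested, 13321 had their gene ID in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. Some genes of the lists are not analysed here. Values were taken as log2 of the signal plus a pseudocount of 17.1, the median over arrays of the 20th percentile signal, so folds of dim genes are understated. A probe set was kept if it exceeded the 40th percentile of its array on at least 6 arrays, which left 29550, and 24468 of them with 1 gene. The probe set of highest mean stood for each gene, giving 13390 genes, 6237 of which had more than 1 kept probe set.

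Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The tests of the groups and of the lists, except the exact permutation of list means, the gene lists (19 of biology and 14 of cell type markers) and all but 7 of the alternative settings were fixed before the data were examined, whereas most tests of what lay behind single patterns were chosen later. Lists were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, both planned, of which fry tests whether the genes of a list move one way and compares them with no other genes. The exact permutation of list means, over all splits and within scan days, was added after random splits had been seen to give as many lists by camera as the real groups. Genes were named by rule: the 12 largest rises and 8 largest falls past the threshold with an established symbol and a mean above the array median in the higher group, up to 2 rises and 2 falls of each list or its member of smallest p, and a short set of macrophage genes wherever measured. Arrays were classed by nearest centroid on 50 genes chosen without the array. The spread within groups was tested with 100000 permutations, and 10000 under the alternatives.

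On data simulated for the comparison of urethane with control, over 13390 genes with independent errors, limma recovered 31% of genes changed 1.5-fold and 72% of genes changed 2-fold, and 5.50% of the 109 genes called were unchanged. Of 100 unchanged lists 0 were called there, but the simulated genes were independent, unlike the genes of these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

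The results were recomputed under 46 other settings: 17 that left out 1 array, 22 others planned, and 7 added after the data were seen, among them fry in place of camera for the count of lists. The settings changed the scaling between arrays, the pseudocount, the filter, the probe set that stands for a gene, the variance model, the covariates and blocks, the arrays used, the number of genes in the classifier, the test of the lists and the fold threshold. Scan day and number range split the arrays identically and were run as 1 block. No 2 arrays held identical values.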

Results

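Cells washed from the airways and air spaces by bronchoalveolar lavage, which in an untreated mouse are mostly alveolar macrophages, were profiled in A/J mice, an inbred strain prone to lung tumours. Untreated mice of matched age (6 arrays) were compared with mice given urethane, a carcinogen that induces lung tumours in this strain (11 arrays), on Affymetrix arrays. Each array is named by the number in its label, and control 6_13 carried 2 numbers. The arrays fell into 2 scan days, which were also 2 chip lots and 2 ranges of these numbers: scan day 1 held 2 control and 5 urethane arrays, and scan day 2 held 4 control and 6 urethane arrays. Values with scan day as a block or within each day are given for the leading genes and lists, and for some others where a call or the size of a difference changed. The trimmed mean signal was 500 on every array, and the 20th percentile signal ran from 9.49 to 66.2, with the highest values on urethane 33, 36 and 35. The number of arrays limits the precision. The labels do not state that each number is a separate mouse, so the p-values measure the spread between these samples, part of which may be technical.

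The comparison asks how lavage cells of urethane-treated mice differ from those of controls. The largest rises were in Fstl1, which encodes a secreted follistatin-like glycoprotein, in Arnt2, a bHLH-PAS transcription factor, and in Bex1. The Fstl1 log2 signal was 7.69 ± 1.61 (SD, n = 6) in controls and 12.11 ± 0.89 (SD, n = 11) after urethane, a log2 difference of 4.42 (SE 0.50, limma adjusted p = 3.0e-05). It was 4.60 with scan day as a block, 4.64 on scan day 1 and 4.57 on scan day 2. Lrg1, a leucine-rich glycoprotein, rose by 2.88 (SE 0.42) and Ptgir, the prostacyclin receptor, rose by 2.53 (SE 0.30). Marcks, Rbp4 (the retinol carrier), Cyp4a12a, Myrf, Wfdc17, Cdo1 (cysteine dioxygenase) and Ms4a4b completed the 12 largest rises, with log2 differences from 2.21 for Marcks down to 1.98 for Ms4a4b. All 11 urethane arrays lay above the control mean for each of these 12 genes. Arnt2 rose by 3.76 (SE 0.50) and Bex1 by 3.53 (SE 0.84). The 3 probe sets of Arnt2 gave log2 differences from 0.76 to 3.76. Arnt2 was at 9.32 in control 36 and at most 6.34 in the other controls. Control 36 was the highest control for each of the 12 largest rises except Cyp4a12a and Cdo1. Lrg1 was at 11.77 there, near the urethane mean of 11.60, and at most 9.03 in the other controls. Fstl1 was at 10.58 in control 36 and at most 8.55 in the other controls. Within scan days 1 and 2 the differences were 3.36 and 4.22 for Arnt2, 2.50 and 4.75 for Bex1, 3.55 and 2.50 for Lrg1, and 2.62 and 2.60 for Ptgir. The 7 probe sets of Marcks gave log2 differences from 0.31 to 2.62. Arnt2, Bex1 and Cdo1 exceeded the 40th percentile signal of the array on 2 control arrays each, so their folds rest on control signals near the low end.

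**Figure D1:**
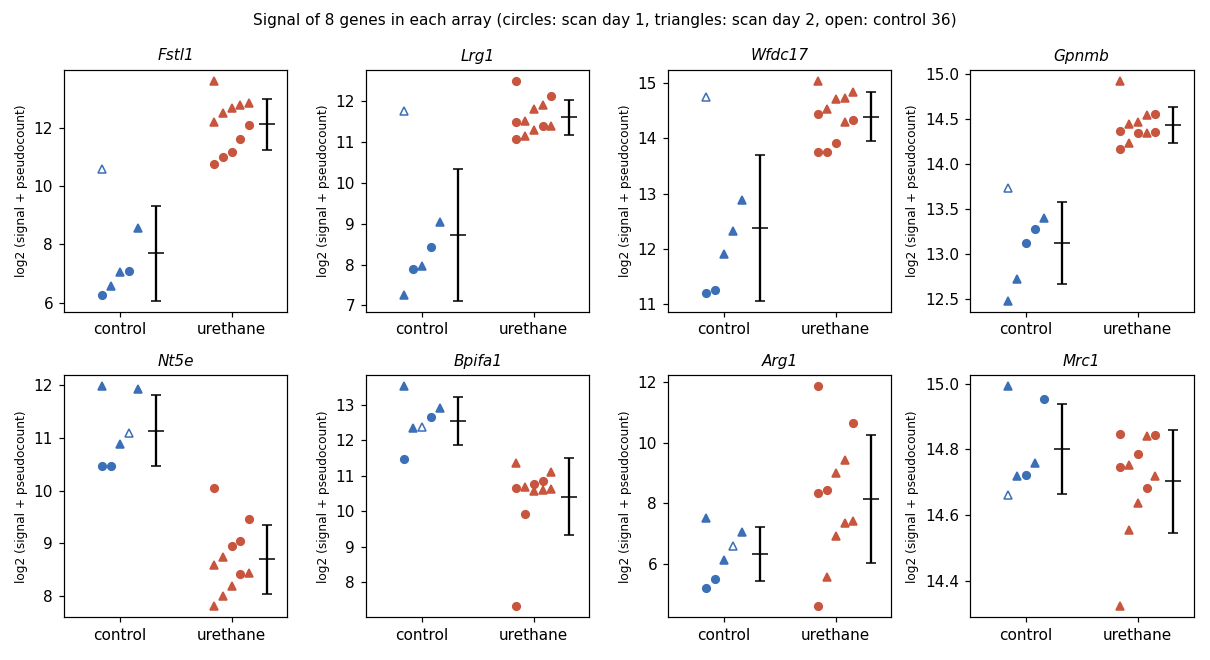
Log2 signal with pseudocount (vertical axis) of 8 genes in 6 control and 11 urethane arrays; each point is 1 array (circles, scan day 1; triangles, scan day 2; open symbol, control 36), and black bars give the mean and SD of the group. Fstl1 averaged 7.69 in controls and 12.11 in urethane arrays, Nt5e averaged 11.14 and 8.69, and Mrc1 averaged 14.80 and 14.70.

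The largest falls were in Nt5e, the ecto-5'-nucleotidase that makes adenosine from AMP, which went from 11.14 ± 0.68 (SD, n = 6) to 8.69 ± 0.66 (SD, n = 11), a log2 difference of -2.45 (SE 0.29, limma adjusted p = 4.5e-05), and in Hmcn1 (-2.39, SE 0.48) and the water channel Aqp1 (-2.36, SE 0.37). Tnfsf13b, which encodes the B cell survival factor BAFF, fell by 2.01 (SE 0.24), and Acaa1b, a peroxisomal thiolase, fell by 1.99 (SE 0.45). Bpifa1 and Cyp2f2, both secretory airway genes, and Ttll7 completed the 8 largest falls, at -2.15, -1.70 and -1.69. All 11 urethane arrays lay below the control mean for each. The 3 probe sets of Nt5e gave differences from -2.45 to -0.17, and its difference was -2.48 with scan day as a block, -1.29 on scan day 1 and -3.19 on scan day 2. Within scan days 1 and 2 the differences were -2.19 and -2.78 for Hmcn1, -1.73 and -2.59 for Aqp1, -1.58 and -2.36 for Tnfsf13b, and -1.33 and -2.68 for Acaa1b.

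In all, 421 of 13390 genes passed an adjusted p of 0.05 in limma, 268 higher and 153 lower after urethane, and 289 of them differed at least 1.5-fold (184 higher and 105 lower). With scan day as a block the counts were 1038 and 519. Scan day 1 alone gave 974 genes and scan day 2 alone gave 636, and 195 genes passed on each day separately with the same sign. Over all 13390 genes, which are not independent replicates, the log2 differences of the days correlated at 0.04. The 20th percentile signal, urethane minus control, differed by -0.85 in log2 on scan day 1 and by 0.40 on scan day 2. Low signals thus moved with the group in opposite directions on the 2 days, which limits the comparison of days for dim genes. The groups did not overlap for 63 genes, and a complete separation has a chance of 0.0162% for any 1 gene. The pooled count was 634 without control 36, and 220 and 218 without control 33 or control 35. Among the 61 genes named by rule that passed, all 11 urethane arrays lay on the side of the change, except for Gpr18, Adam8, Jun and C5ar1 with 10 of 11. The 61 were chosen for passing on these same arrays, so this adds no separate support. All 61 also passed with scan day as a block, as did all 421. For 17 of the 61 the size differed over 2 times between days, among them Cd83 (-0.09 on scan day 1 and -1.09 on scan day 2), C5ar1 (-0.27 and -1.34), Napsa (-0.41 and -1.34), Epcam (-0.91 and -2.20) and S100a8 (1.11 and 2.39). Of the 61, 0 had an interaction past the threshold (lowest limma adjusted p = 0.0904). Only 11 of all 13390 genes had one, so this does not set the named genes apart.

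Genes of cholesterol synthesis were higher together after urethane: 15 of the 19 measured members rose, 0 fell and 4 did not pass, with 18 past the threshold when adjusted over the list alone. Sqle, squalene epoxidase, rose by 1.22 (SE 0.23) and Idi1, an isopentenyl-diphosphate isomerase, by 1.19 (SE 0.20). The list mean was 10.04 ± 0.34 (SD, n = 6) in controls and 10.85 ± 0.24 (SD, n = 11) after urethane, and all 11 urethane arrays lay above the control mean. Control 36, at 10.72, was the highest control. The camera test with a preset correlation gave an adjusted p = 3.9e-27, and with an estimated correlation an adjusted p = 0.050, under the threshold before rounding. The median log2 difference was 0.76 on scan day 1 and 0.85 on scan day 2. With scan day as a block, 17 members rose and the estimated correlation gave an adjusted p = 0.0514, which did not pass.

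Among genes of lipid uptake, storage and efflux, 5 of 24 rose and 2 fell. Fabp4 and Fabp5, fatty acid binding proteins, rose by 1.03 (SE 0.16) and 0.79 (SE 0.12), whereas Cidec, a lipid droplet protein, fell by 1.62 (SE 0.40) and Abca1, the cholesterol efflux pump, fell by 0.83 (SE 0.16). The list as a whole did not pass (camera adjusted p = 0.131). In the lysosome list 5 of 27 rose and 0 fell (camera adjusted p = 2.8e-06, median 0.09; adjusted p = 0.306 with an estimated correlation). Gpnmb, a transmembrane glycoprotein of lysosomes and macrophages, rose by 1.31 (SE 0.14) and the cathepsin Ctsl by 0.82 (SE 0.16). The other members that rose, named after their values were seen, were Gla, Lgmn and Ctsk.

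None of the general macrophage and leukocyte markers passed. Their log2 differences were 0.01 for Cd68, -0.08 for Csf1r, -0.10 for Mrc1, -0.00 for Marco, -0.06 for Chil3 and -0.08 for Ptprc (limma adjusted p from 0.691 to 0.996). Of the 19 alveolar macrophage markers, 2 rose and 2 fell (camera adjusted p = 0.131): Fabp4 as above, Car4 rose by 0.96, Fabp1 fell by 1.06 and Cidec as above. The list passed as lower with scan day as a block, where 2 rose and 7 fell (camera adjusted p = 0.0017; adjusted p = 0.312 with an estimated correlation). In the alternative activation list 0 of 19 passed (camera adjusted p = 0.194). With scan day as a block 1 member passed as lower, Il1rn (-0.54, limma adjusted p = 1.6e-04), and 1 as higher, Clec10a (limma adjusted p = 0.0193), named after its value was seen, and the list did not pass (camera adjusted p = 0.339). Arg1 averaged 6.32 ± 0.89 (SD, n = 6) in controls and 8.14 ± 2.12 (SD, n = 11) after urethane, and Retnla 7.11 ± 2.82 and 9.40 ± 2.40, with log2 differences of 1.82 and 2.28 that did not pass (limma adjusted p = 0.254 and 0.325). The Arg1 difference was 3.43 on scan day 1 and 0.80 on scan day 2, and the change between days did not pass (interaction, limma adjusted p = 0.359). The Retnla difference was 5.29 on scan day 1 and 0.50 on scan day 2 (interaction, limma adjusted p = 0.243). Retnla passed under 2 alternatives, scan day 1 alone and the RNA quality ratios as covariates, and over all alternatives its adjusted p ran from 0.0295 to 0.840. Mmp12, the macrophage elastase, and Igf1 had differences of 1.15 and 1.92 that did not pass in the pooled fit (limma adjusted p = 0.130 and 0.0604) and passed with scan day as a block (0.0089 and 6.0e-04), and over all alternatives their adjusted p ran from 5.2e-04 to 0.548 and from 9.3e-05 to 0.185. Within scan days 1 and 2 their differences were 2.44 and 0.60 for Mmp12 and 2.97 and 1.66 for Igf1 (interaction, limma adjusted p = 0.111 and 0.335). In the classical activation list Il1a rose by 0.79, Gpr18 fell by 0.52, and the list did not pass (camera adjusted p = 0.883). The Nos2 probe set was below the 40th percentile of the array on all 17 arrays and was not tested.

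**Figure D2:**
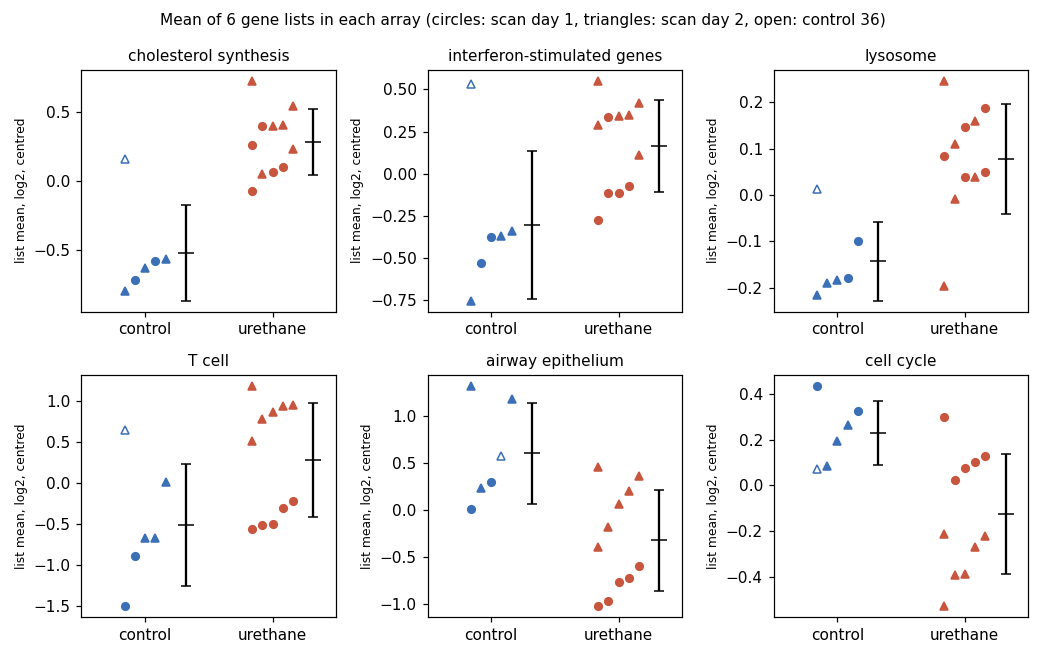
Mean log2 signal of the members of 6 gene lists in each array, centred on the mean over the 17 arrays (vertical axis); each point is 1 array (circles, scan day 1; triangles, scan day 2; open symbol, control 36), and black bars give the mean and SD of the group. The cholesterol synthesis mean differed between the groups by 0.80, and the airway epithelium mean by -0.92.

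In the interferon-stimulated list 2 of 26 rose, Ifi47 (0.68, SE 0.17) and Irf9 (0.55, SE 0.14), and 7 passed when adjusted over the list alone (camera adjusted p = 5.1e-08; adjusted p = 0.306 with an estimated correlation). Without control 36 the number that rose was 11, and with scan day as a block it was 6. In the MHC class II list H2-DMb2 fell by 0.63 and the other 10 did not pass (camera adjusted p = 0.0016; adjusted p = 0.306 with an estimated correlation), and the median was 0.01 on scan day 1 and -0.43 on scan day 2. Among chemokines Ccl9 rose by 1.30 (SE 0.16), Ccl3 rose by 0.83 and Cx3cl1 fell by 1.01, and the list did not pass (camera adjusted p = 0.702). Of the receptors of myeloid cells, the Fc receptor Fcgr4 rose by 0.86 (SE 0.11) and the C-type lectin Clec4e fell by 1.0 (SE 0.14), with a camera adjusted p of 0.212. C5ar1 fell by 0.86 in the complement list (camera adjusted p = 0.841), Adam8 rose by 1.17 in the list of matrix proteases and matrix proteins (0.131), and Inhba rose by 1.46 among growth factors (0.212).

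Markers of the airway epithelium, which lines the passages the lavage fluid crosses, were lower after urethane: 7 of 18 fell, 0 rose, and 11 fell when adjusted over the list alone. Bpifa1 and Cyp2f2 are described above. The list mean went from 8.89 ± 0.53 (SD, n = 6) to 7.97 ± 0.53 (SD, n = 11), and 0 of 11 urethane arrays lay above the control mean. The camera adjusted p was 1.5e-09, and the call was lost with an estimated correlation (adjusted p = 0.292). The median difference was -0.93 on scan day 1 and -0.78 on scan day 2. Epcam, an epithelial adhesion molecule, fell by 1.60 (SE 0.30) in the general epithelium list, and Napsa fell by 0.97 among alveolar type 2 markers, while those lists did not pass (camera adjusted p = 0.147 and 0.712). The fall of Napsa leaned on control 37, at 12.27 against at most 10.77 in the other controls. Alveolar type 1 markers had a median of -0.32 with 0 members past the threshold (camera adjusted p = 0.0403; adjusted p = 0.348 with an estimated correlation).

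Among T cell markers 3 of 18 rose (camera adjusted p = 4.4e-06, median 0.63; adjusted p = 0.348 with an estimated correlation). Ms4a4b is given above, Cd3d, a chain of the T cell receptor complex, rose by 1.84 (SE 0.48), and the third, named after its value was seen, was Il7r. Cd3d exceeded the 40th percentile signal on 1 of 6 control and 11 of 11 urethane arrays. Among neutrophil markers S100a8 rose by 1.73 (SE 0.44), Wfdc17 rose as above, and so did Wfdc21, named after its value was seen (camera adjusted p = 0.0796 for the list). The neutrophil list passed with scan day as a block (camera adjusted p = 0.0459; adjusted p = 0.426 with an estimated correlation) and without control 36 (camera adjusted p = 0.0061). Its mean difference of 0.40 leaned on urethane 34, at 2.37 above the mean over the 17 arrays against at most 0.65 in the other urethane arrays, and was 0.18 without that array (camera adjusted p = 0.453). The neutrophil median was -0.05 on scan day 1 and 0.85 on scan day 2. Cx3cr1 fell by 1.57 among monocyte and interstitial macrophage markers (camera adjusted p = 0.841), with -0.24 on scan day 1 and -2.39 on scan day 2 (interaction, limma adjusted p = 0.156), and Cd83 fell by 0.73 among dendritic cell markers (0.190). The lists of B and plasma cells, NK and cytotoxic lymphocytes, eosinophils, basophils and mast cells, endothelium and fibroblasts, and erythroid cells had 0 members past the threshold and camera adjusted p of 0.188, 0.159, 0.694, 0.902 and 0.482. The NK list, with scan day as a block, passed as higher (camera adjusted p = 0.0459; adjusted p = 0.312 with an estimated correlation), and 1 member then passed in each of these lists except the erythroid one: Jchain, Ccl5 and Cdh5 were higher and Alox5 was lower, of which Ccl5 was named after its value was seen.

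Cell cycle genes were lower as a list: 1 of 35 fell, the replication licensing factor Mcm2 (-0.65, SE 0.17), and 10 fell when adjusted over the list alone (camera adjusted p = 1.4e-09, median -0.35; adjusted p = 0.306 with an estimated correlation). The median was -0.25 on scan day 1 and -0.53 on scan day 2, and 16 members fell with scan day as a block. In the list of p53 targets and DNA damage response, Phlda3 rose by 1.04 (SE 0.16), Trp53inp1 rose by 0.58, a further member, Zmat3, rose as well, and Xpc, a DNA repair gene, fell by 0.64 (SE 0.12), with a camera adjusted p of 0.0018 and an adjusted p = 0.306 with an estimated correlation. Of the antioxidant genes, the metallothioneins Mt2 and Mt1 fell by 1.08 and 0.63, Gstm1 rose by 0.43, and 1 more, Gclm, fell (camera adjusted p = 0.0203; adjusted p = 0.563 with an estimated correlation). Zmat3 and Gclm were named after their values were seen. Hk2 rose by 0.69 and Ndrg1 fell by 1.03 in the list of glycolysis and hypoxia response (camera adjusted p = 0.283). Jun and Atf3 rose by 0.66 and 0.59 and Egr1 fell by 0.73 among immediate early genes (0.283). Oxidative phosphorylation and the unfolded protein response had 0 members past the threshold (camera adjusted p = 0.142 and 0.860). In the unfolded protein response 2 members rose and 1 fell with scan day as a block.

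With scan day as a block 12 lists passed camera with a preset correlation, those of alveolar macrophages, neutrophils and NK cells among them, and with an estimated correlation the lowest adjusted p was 0.0514. Of the lists that passed in the pooled fit, the camera adjusted p was 1.1e-23 for cholesterol synthesis, 1.1e-08 for airway epithelium, 5.2e-05 for lysosome, 1.1e-07 for interferon-stimulated genes, 8.6e-10 for T cells, 1.4e-14 for cell cycle, 9.1e-04 for p53 targets, 0.0034 for MHC class II and 0.0051 for antioxidant genes, and 0.0602 for alveolar type 1 epithelium, which no longer passed. The number of members that rose was 7 for T cells and 7 for p53 targets, and 6 antioxidant genes fell. Without control 36 also 12 lists passed, with neutrophils, dendritic cells (camera adjusted p = 0.0248) and matrix proteases (camera adjusted p = 0.0354) gained and alveolar type 1 epithelium lost (camera adjusted p = 0.0680). On scan day 1 and scan day 2 the median differences were 0.19 and 0.09 for lysosome, 0.33 and 0.50 for interferon-stimulated genes, 0.69 and 0.98 for T cells, 0.25 and 0.21 for p53 targets, -0.09 and -0.21 for antioxidant genes, and -0.35 and -0.25 for alveolar type 1 epithelium. The median lay below 0 and the mean and camera direction above it for the lists of complement, chemokines, monocytes and endothelium, and the reverse held for classical activation.

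In all, 10 of the 33 lists passed the camera test with a preset correlation, 5 higher and 5 lower. The RNA quality ratios as covariates gave 9 lists, 7 higher and 2 lower. The lower calls of MHC class II antigen presentation (camera adjusted p = 0.111), antioxidant response (0.119) and alveolar type 1 epithelium (0.0649) ended there, and oxidative phosphorylation (9.5e-06) and activating and inhibitory receptors of myeloid cells (0.0026) passed as higher. With an estimated correlation 1 list passed, cholesterol synthesis, and with fry 2 passed, cholesterol synthesis and airway epithelium. An exact permutation of each list mean over the 12376 splits of the arrays passed 2 lists after adjustment, cholesterol synthesis (adjusted p = 0.0133) and lysosome (adjusted p = 0.0320). Restricted to the 4410 splits within scan days it passed 12, not all of them those of camera with the block. MHC class II (exact permutation adjusted p = 0.0703), neutrophils (0.142) and NK cells (0.0641) did not pass it. Growth factors (0.0086), dendritic cells (0.0412) and glycolysis and hypoxia response (0.0412) did. Of 100 splits of the arrays, the real one included, 28 gave at least 10 lists by camera with a preset correlation.

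The study's own macrophage signature was not used here; a classifier was instead built from these arrays. When each array was left out and classed by the 50 genes that best separated the other 16, 16 of 17 were classed correctly: 11 of 11 urethane and 5 of 6 control arrays. Control 36 was classed with urethane. None of 100 permutations of the labels classed as many correctly (permutation p = 0.0099, the smallest that they can give), and their highest number was 14.

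The 3'/5' signal ratio of the beta-actin control probe sets, a sign of RNA integrity, averaged 0.151 ± 0.063 (SD, n = 6) in log2 in controls and 0.213 ± 0.045 (SD, n = 11) after urethane (exact permutation p = 0.0353, and 0.0706 adjusted over 2 ratios), with differences of 0.020 on scan day 1 and 0.090 on scan day 2. The Gapdh ratio was -0.177 ± 0.167 (SD, n = 6) and -0.203 ± 0.163 (SD, n = 11) with an exact permutation p = 0.763. The mean distance between arrays of a group, per gene in log2 units, was 0.779 in both groups (permutation p = 1.0, two-sided). The difference, urethane minus control, was -0.23 on scan day 1 (permutation p = 0.290) and 0.05 on scan day 2 (permutation p = 0.602). The distance was 0.157 lower in urethane than in control arrays when urethane 33, 35 and 36 were left out, a setting chosen after their low signals were seen. The effect of urethane differed between the 2 number ranges for 11 genes in limma, 2 with a more positive effect in the higher range, and 2334 had an unadjusted p under 0.05. The lower range holds 2 controls. The count was 663 without control 37, 88 and 23 without urethane 31 and 32, 19 without control 6_13, 6 and 4 without urethane 9 and 34, and 0 when any other single array was left out.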

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

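The tests of control 36, of scan day, of low signals, of the airway markers and of lists in splits within scan days were chosen after the results were seen; those of T cells and of the other splits were not. Among the 6 controls, 117 results (named genes, list means and array measures) were tested for an array far from the rest, where chance flags about 1 in 20 of independent results. The test found 15, 11 of them for control 36. The 117 results share arrays and genes, so the number found cannot be compared with 1 in 20. By the gap over the range, control 36 stood apart for Arnt2 (0.676), Hmcn1 (0.626), Acaa1b (0.823), Irf9 (0.677), Ctsl (0.629), Mt1 (0.727), Phlda3 (0.668), Car4 (0.659), S100a8 (0.817) and the means of the interferon-stimulated (0.681) and cholesterol synthesis lists (0.757). Control 37 stood apart for Atf3 (0.665), Napsa (0.829) and the 18S rRNA probe set (0.772), whose log2 signal of 11.70 compares with at most 7.97 in the other controls. Control 6_13 was low for the mean of B and plasma cell markers (0.723).

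Control 36 lay near the urethane arrays and was the 1 array classed wrongly. An exchange with a urethane array would leave a partner classed as control, and 0 of the urethane arrays were; urethane 3 was so classed with a scan day block or with 200 genes, and urethane 9 in the lower number range alone, both scanned on the other day. A urethane sample under a wrong label was tested with references from both scan days. The genes that rose had gone a median of 0.809 of the way from the other controls to urethane. This lay inside the range of the urethane arrays (0.337 to 1.62). The genes that fell had gone 0.653, below the lowest (0.717) by less than the SD of these arrays (0.187). That version does not decide. With references from the same scan day, a version written after the first, both lay below the lowest urethane array (0.610 against 0.777, and 0.619 against 0.860 with an SD of 0.0752). The same-day values argue against a wrongly labelled sample like the urethane arrays of that day. The rule set for this test asked both versions to lie below the lowest urethane array by over 1 SD, so a wrong label stays open. RNA or cells of a urethane sample mixed into control 36 may account for where it lay, and would put genes that rose and genes that fell at 1 fraction. The 2 fractions differed by 0.156 with references from both scan days (SD 0.251 over the other arrays), too coarse to decide, and by -0.0089 from the same scan day (SD 0.0494). A change in that mouse itself stays open too, and no biological explanation was tested.

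The higher cholesterol synthesis genes were set against low signals, scan day and T cells, and the values argue against each as the whole cause. With the 20th percentile signal of the array as a covariate, which moved the count of genes from 421 to 872, the mean shift was 0.80 against 0.804 without it. That signal differed little between the groups (-0.16 in log2, exact permutation p = 0.687), so this covariate could hardly move the shift. By day it differed in opposite directions (-0.85 on scan day 1 and 0.40 on scan day 2), while the list median was higher on both (0.76 and 0.85). With scan day as a block the mean shift was 0.831. T cells, 3 of whose 18 markers rose (the list did not pass with an estimated correlation, adjusted p = 0.348), were tested with the mean of their markers as a covariate: the shift was 0.624 and the list still passed by camera with a preset correlation (adjusted p = 9.4e-20; over the alternatives its adjusted p ran from 6.1e-41 to 0.050, and it did not pass with an estimated correlation and scan day as a block together, at 0.0514). A response of the lavage cells to treatment may remain, as may other changes in cell makeup, and these data do not separate them.

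Whether the lower airway epithelium markers reflect fewer airway cells in the lavage was not settled. Of 13 markers above the array median in controls, 13 were lower after urethane, with log2 differences from -2.15 to -0.542. Choosing them by their control mean favours markers that are lower after urethane. Of all 18 markers tested, 1 had a positive difference. Ltf, 1 of the 13, is also in the neutrophil list. Fewer cells would make the markers vary together within a group, and their mean pairwise correlation was 0.378 (highest of 1000 random lists 0.346), but it was 0.259 with scan day removed as well (highest random list 0.261), so part of it follows scan day and the test leaves this open. Scan day as the whole cause of the shift is argued against by -0.825 with scan day as a block. A lower level in the same number of cells stays open too.

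The effect of urethane differed between scan days, which were also the number ranges, for 11 genes, and by camera with a preset correlation for 9 lists. The median differences, day 2 minus day 1, were -0.570 for complement, -0.238 for oxidative phosphorylation, -0.491 for monocyte and interstitial macrophage markers, -0.484 for MHC class II, -0.278 for receptors of myeloid cells, -0.321 for cell cycle, -0.186 for the unfolded protein response, 1.30 for erythroid cells and -0.240 for alveolar macrophage markers. With an estimated correlation the lowest adjusted p of these was 0.554. The 20th percentile signal also differed between the groups in opposite directions on the 2 days (-0.85 and 0.40 in log2). Whether that moved the differences of these lists was not tested.

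Of 100 splits of the arrays into 6 and 11, the real one included, 3 gave as many genes as the real 421 (highest other 2071) and 3 as many as the real 289 changed at least 1.5-fold (highest other 1588). These shares are under 0.05, but 100 splits measure them coarsely, so chance is not firmly excluded for these counts. The split with 2071 genes set urethane 33, 35 and 36 with control 14, 33 and 37 against the rest, which points to a structure of the arrays along the low signals: the 20th percentile signal differed, the other 11 arrays minus these 6, by -1.29 in log2. The next, with 467 genes and 11 lists, largely followed scan day, and its 20th percentile signal differed, other 11 minus these 6, by 1.04. Of 100 splits within scan days, 1 gave as many as the real 1038 genes with scan day as a block (highest other 124). For the lists, 28 of 100 splits gave at least the real 10 (highest other 15), and with scan day as a block 11 of 100 splits within scan days gave at least the real 12 (highest other 18), so chance cannot be excluded for either count. Tested singly by exact permutation of their means within scan days, 12 lists passed after adjustment, not all of them those of camera with the block. Growth factors, dendritic cells and glycolysis and hypoxia response were among them, and MHC class II, neutrophils and NK cells were not.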

How the results depend on the processing

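The settings with urethane 33, 35 and 36 left out, with the 20th percentile signal, with scan day and control 36 left out, and with exact permutation or fry in place of camera for the lists were chosen after the data were seen, fry having been planned only beside camera. The 421 genes became 248 with median centring (203 higher and 45 lower), 250 with no variance trend, 1038 with scan day as a block, 974 in the lower and 636 in the higher number range, 872 with the 20th percentile signal, 1535 with that and scan day, and 1199 with scan day and without control 36. The 289 genes changed 1.5-fold became 188 with no variance trend, 519 with scan day, 612 and 505 in the lower and higher range, 440 with the 20th percentile signal, 621 with that and scan day, 627 with scan day and without control 36, and 126 at 2-fold. Leaving out 1 array gave 218 (control 35) to 634 genes (control 36), and 176 (control 33) to 428 (control 36) at 1.5-fold. The share of higher genes was 63.7%, and 81.9% with median centring, 49.5% with the 20th percentile signal, 49.7% in the higher range, and 48.3% and 50.5% on the 6 arrays below without and with the block. Without urethane 33, 35 and 36, 223 genes were higher and 185 lower, and at 1.5-fold 120 were higher and 151 lower. The 10 lists became 1 with an estimated correlation, 2 with exact permutation and 2 with fry. The beta-actin ratio difference of 0.061 was 0.077 with quantile normalization (adjusted p = 0.0205) and 0.048 to 0.083 with 1 array left out, past the threshold without control 37 (adjusted p = 0.0096) or urethane 3 (adjusted p = 0.0265). It was larger on the 6 arrays below, where the ratio ran from 0.083 to 0.133 in controls and from 0.223 to 0.267 in urethane arrays. The 11 genes whose effect differed between number ranges became 0 with quantile normalization, 4 times the pseudocount, array weights, RNA quality ratios, the 20th percentile signal or urethane 33, 35 and 36 left out, 27 with median centring, 2 and 5 with probe sets averaged or tested singly, 3 with no variance trend, and 0 to 663 with 1 array left out. The spread difference of 1.6e-05 was -0.157 without urethane 33, 35 and 36 (permutation p = 0.0223), -0.163 with the 20th percentile signal (0.0067) and -0.105 with that and scan day (0.0304). Classification was correct for 85.7% to 100% of arrays. Of 61 named genes past the threshold 37 passed with every array left out in turn, and of 10 lists 8 did. Among the genes that did not, Gpr18 passed under 12 of 38 alternatives, Adam8 and C5ar1 under 18 each, and Mcm2 and Fabp1 under 20 each. The lists that did not were antioxidant response (camera adjusted p = 0.119 without urethane 33) and alveolar type 1 epithelium (camera adjusted p = 0.0995 without control 35). The cause was not tested for these changes. Classification, spread and the difference between ranges were not run on the 6 arrays below, nor the last within 1 range or with scan day as a block. Genes near the low signals are limited by signal over background.

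The numbers 33, 35 and 36 occur in both groups, but arrays of 1 number did not deviate together (correlations -0.044, -0.183 and -0.126), so they were not taken as pairs. On those 6 arrays 3145 genes passed with a replicate block and 3251 with no block, and 2259 and 2242 at 1.5-fold. The 3 urethane arrays among them are those with raised low signals. With and without the block, oxidative phosphorylation (-0.232), complement (-0.376), receptors of myeloid cells (-0.247) and monocyte markers (-0.442) turned lower, and camera ranked lysosome genes low although their mean was 0.066. In the lower number range camera ranked MHC class II high with a mean of -0.00043. The cause was not tested.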
